A study of Arabidopsis thaliana with 4 samples.

How the data were processed

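Transcript levels were measured in shoots of wild-type Arabidopsis thaliana seedlings (the Col-0 strain) on 4 microarrays, 2 for each treatment. Per the labels, the plants grew on upright plates in 24 h light for 14 days and were covered for 5 min with liquid holding 100 uM abscisic acid (ABA), basal salts and 0.1% Tween 20, a wetting agent, or with mock solution. Shoots were cut from the roots and collected 4 h later, in pools of 20 to 24 seedlings. Per the labels' protocols, total RNA was extracted on silica columns and amplified RNA carrying biotin was hybridised to a 1-colour array. The probe set names follow the pattern of Affymetrix designs.

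The deposited values are intensities on a linear scale, 1 per probe set and array, processed by the authors. The software, background correction, summarisation and scaling behind these deposited intensities are not given in the sources used here. They reach from -50.9 to 2223, so some background was subtracted, and between 12.8% and 13.7% of probes lay below 0 on each array. Detection calls, scan dates and slides were not used here. The median intensity over tested probes was 12.4 and 12.9 on the ABA arrays and 16.9 and 17.0 on the mock arrays, so the arrays did not share a median. Arrays give no read depth, and their number, 2 per group, limits the precision.

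Of 19658 probe sets, 287 control sets (spiked transcripts, housekeeping sets and vector sequences) were left out, and 19371 were tested. Gene names came from the array's public annotation, updated to symbols of the TAIR10.1 assembly by gene identifier for 11547 probes and by locus code for 45, while 6 kept the annotation's name. In all, 11598 probes had 1 gene name, 0 had several, and 7773 are unnamed here, which does not mean that they lack a gene. They name 11371 genes, mostly by locus code. The array's own genome build is not given in the sources used here, so no coordinates are printed. Where 214 genes had more than 1 probe, the probe with the highest mean over all 4 arrays stood for the gene. In 24 such genes at least 2 probes passed the threshold, and 0 of these genes had probes called in opposite directions. Probe sets whose names mark them as able to bind related transcripts numbered 1735.

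Intensities below 0 were set to 0, 16 was added and log2 was taken, so a fold change on this scale understates the change of dim genes. The design fixed before the data were examined named log2(intensity + 16). Setting negatives to 0 was added because some values stayed below 0 after adding 16. In all, 1194 probes were at 0 or below on every array and carry no change. The scaling between arrays was kept as deposited. ABA was compared with mock by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Nothing was fitted besides the treatment. The labels call the replicates biological, and each was a pool of separate seedlings.

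Gene lists were tested with limma's camera at a preset correlation of 0.01 on 1 probe per gene, for lists with at least 3 members named here, and adjusted over the lists tested. Camera asks whether a list moved relative to the other genes, so a shift of equal size in all genes does not move it. On the log2 scale used here the shift grew with intensity, which may come in part from the constant added before log2 was taken. A list of bright genes can be moved by this shift, and results after quantile normalization are given for this reason. Camera's unit is the gene, and genes are not independent replicates, so each result is also given with a correlation estimated from the data. With 2 arrays per group this estimate is imprecise. It ran from -0.50 for the early auxin list to 0.96 for the plastid ribosomal list. A call lost with it shows that the call depends on the correlation assumed, not that the genes move together. Before the data were examined, 32 lists had been fixed. One of them, ribosomal proteins, rested on gene titles, which were not used here. Of the remaining lists, 14 had no member named here, and 5 could be tested. They held 420 loci, of which 41 were named. A further 18 lists (8 of loci, the ribosomal one included, and 10 families by symbol) were written after the annotation had been seen but before any comparison of the groups, and were adjusted as their own family.

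Most genes named in the text follow a rule fixed in advance. It takes the 10 highest and 10 lowest changes among named genes past the threshold whose ABA arrays both lie on one side of both mock arrays. From each fixed list it takes up to 3 members past the threshold with the largest change, or the 2 largest where none passed. It also called for 11 standard ABA-response and reference genes, of which 0 had a probe named here. Further members of the fixed lists (COR47, COR15B, KIN2, LEA18, LHCB4.1, LHCB1.5, PORB, CHLI2, EXPB1, EXPA4 and XTH33), and members of the added lists and of gene families, were chosen after their values were seen.

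The analysis was tested on simulated data for the same 19371 probes, drawn with the real means and residual spreads, with changes placed in probes above the 40th percentile of mean intensity. Of 100 probes changed by 1 on the log2 scale 25% were recovered, and of 100 changed by 2 on that scale 56% were recovered, with median estimates of 0.996 and 2.00 and 2 false calls. Far fewer probes were changed there than the 4574 called in the data. The adjustment depends on the share of changed probes, so these recoveries do not carry over to the real fit. Across n = 19371 probes camera gave p = 4.45e-38 for the changed list and called 0 of 20 unchanged lists. Probes were drawn independently, so this does not test camera on genes that move together. The prior degrees of freedom in the real fit were 0.749, and with 2 arrays per group the smallest adjusted p in the main setting was near 0.0166. These degrees of freedom do not alone set that limit. With a floor of 32 they were 0.659, and AT2G41190 had a limma adjusted p of 0.000211.

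Alternatives fixed in advance were quantile normalization, median centring, a filter for probes above the 40th percentile of mean intensity, the replicate number as a block, leaving out each array in turn, pseudocounts of 1 and 64, a floor of 32, an intensity trend in eBayes, 1 probe per gene, limma's treat against a change of 1.5-fold, an adjusted p under 0.01, camera with an estimated correlation, fry, and the mean over a gene's probes. Scaling on 9 spiked control sets, and quantile normalization together with the filter, were chosen after seeing the data.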

Results

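Shoots of 14-day-old Arabidopsis seedlings were profiled 4 h after a 5 min dip in 100 uM ABA or in mock solution, with 2 arrays per treatment, each from a pool of 20 to 24 shoots. Replicate arrays correlated at r = 0.991 in both groups and ABA arrays correlated with mock arrays at r = 0.944 to 0.952, across probes, which are not independent replicates. The median absolute difference between replicates was 0.11 (ABA) and 0.098 (mock) on the log2 scale, against 0.23 to 0.25 between arrays of different treatments.

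The comparison asks which shoot transcripts differed after exposure to ABA, the plant hormone of drought responses and seed maturation. Genes for late embryogenesis abundant (LEA), dehydrin and cold-regulated proteins, which accumulate in drying or chilled tissue, rose in 7 of 7 cases, by up to 5.38 on the log2(intensity + 16) scale, though as a list they did not pass in camera with an estimated correlation (adjusted p = 0.187). Genes for an amino acid transporter family protein, AT2G41190, and a sugar transporter, SAG29, rose by 4.05 and 3.96. Rubisco activase, light-harvesting LHCB4 genes and 58 of 128 cytosolic ribosomal protein genes fell, and part of this lay within an array-wide shift given with the probe counts below. Among the largest falls were a phosphoethanolamine methyltransferase gene, AT1G73600, and a sucrose phosphate synthase gene, ATSPS4F.

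Of the LEA, dehydrin and cold-regulated list, 7 of 7 members named here rose, with a median of 2.79, and 7 also passed when adjusted over the list alone. LEA4-5, a LEA protein gene, went from an intensity of 4.35 ± 0.273 in mock shoots to 833 ± 19.8 after ABA (mean ± SD, n = 2 arrays each; log2 change 5.38, SE 0.029, limma, Benjamini-Hochberg adjusted p = 0.0166). Its mock level lay below the noise level of each array (7.54 or more), so the size of its change is set by the pseudocount, at 3.71 with 64 and 7.28 with 1. KIN1, a cold- and ABA-induced gene, went from 25.3 ± 0.703 to 528 ± 5.05, and COR15A, which encodes a chloroplast protein that protects membranes in freezing, from 79.7 ± 12.6 to 1206 ± 24.9. Their log2 changes were 3.72 (SE 0.025) and 3.68 (SE 0.12). COR47, a dehydrin gene, rose by 2.79, COR15B by 2.56, KIN2 by 1.51 and LEA18 by 1.31. LEA18 was the dimmest, at 1.12 ± 2.89 in mock and 28.0 ± 9.07 in ABA shoots, and after quantile normalization its adjusted p was 0.0667 (limma), leaving 6 of 7 past the threshold. The list's members exceeded other genes by a mean of 3.14 (camera p = 2.42e-13 across n = 11371 genes, adjusted p = 1.21e-12 over 5 lists). With an estimated correlation its p was 0.0374 and its adjusted p = 0.187.

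**Figure D1:**
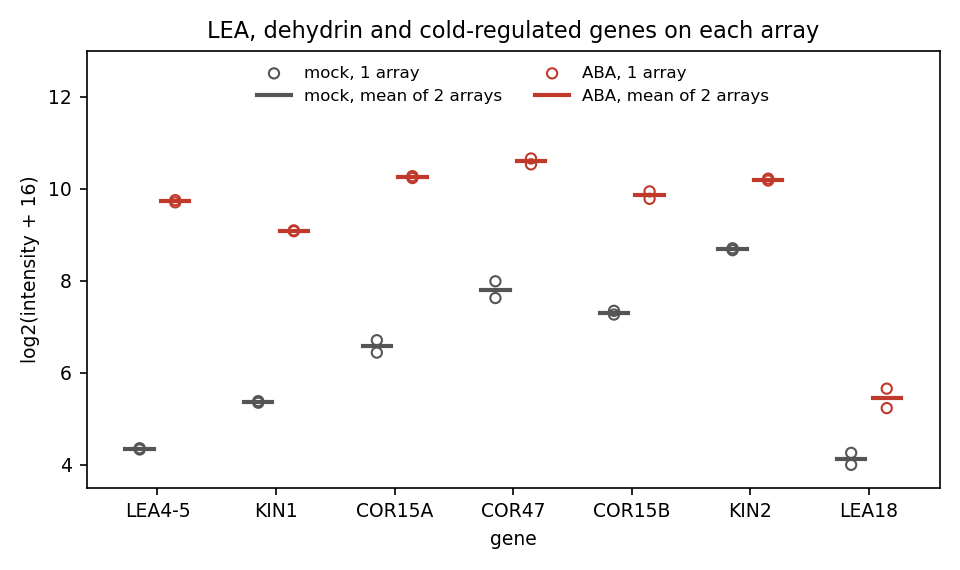
Values of the 7 LEA, dehydrin and cold-regulated genes on each array, as log2(intensity + 16) on the vertical axis, with open circles for the 4 arrays and bars for the mean of each group's 2 arrays. Both ABA arrays lie above both mock arrays for each gene, from LEA4-5, with a log2 change of 5.38, to LEA18, with 1.31.

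The 10 highest named genes also held 7 from outside this list. AT3G02480, a LEA family gene, went from 2.78 ± 3.16 to 645 ± 14.3 (log2 change 5.15, SE 0.15), and AT3G17520, another LEA family gene, from 0.143 ± 0.348 to 206 ± 27.8 (log2 change 3.77). AT1G16850 rose by 4.47, from 9.16 ± 1.01 to 543 ± 25.3. AT2G41190 went from 16.3 ± 2.72 to 518 ± 2.43, and SAG29, a senescence-associated SWEET sugar transporter, from 15.8 ± 6.44 to 476 ± 37.3. AT2G47780, of the small rubber particle protein family, rose by 3.76, and AT5G15500, an ankyrin repeat protein gene, by 3.12. Adjusted p-values (limma, Benjamini-Hochberg) for these 7 genes ran from 0.0166 to 0.0177, and each log2 change was 2.84 or more under quantile, centred and spike scaling. The size depends on the pseudocount, as with 64 in place of 16 the changes of AT3G02480, AT3G17520 and AT5G15500 were 3.41, 2.07 and 1.78. With 1 they were 7.73, 7.45 and 4.72. The mock means of AT3G02480, AT3G17520 and AT5G15500 lay below the noise level of each array (7.54 or more).

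A wider list of LEA and ABA-induced genes, written after the annotation was seen, pointed the same way. Of its 17 members named here, 9 rose and 0 fell, with 10 higher when adjusted over the list alone. Besides AT3G02480, AT3G17520, AT1G16850 and AT2G41190, the risers were PUB19, a U-box ubiquitin ligase gene (log2 change 3.03), AT3G05640, a protein phosphatase 2C gene (2.11), AT3G15670, a LEA family gene (1.68), AT5G66780 (0.88) and AT5G44310 (0.35). The list exceeded other genes by a mean of 1.71 (camera p = 4.00e-12 across n = 11371 genes, adjusted p = 3.60e-11 over 18 added lists). With an estimated correlation its p was 0.0715 and its adjusted p = 0.511. AtLEA4-1 (log2 change 0.61) and the LEA gene at AT2G21490 (-0.47) did not pass, at intensities of 8.78 or less in both groups.

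The 10 lowest named genes fell by 1.66 to 2.46 on the log2 scale. AT4G21870, a small heat shock protein-like gene, went from 84.9 ± 17.5 in mock to 2.07 ± 3.84 in ABA shoots (log2 change -2.46, SE 0.22, limma adjusted p = 0.0247). Its size ran from -1.16 with a pseudocount of 64 to -5.14 with 1, and its call was lost with a pseudocount of 1 (limma adjusted p = 0.0814) and with a floor of 32 (0.0518). AT1G06830, a glutaredoxin gene, went from 166 ± 19.6 to 19.9 ± 1.60 (-2.34), and AT1G73600, the methyltransferase gene of phosphocholine synthesis, from 1081 ± 1.35 to 258 ± 25.2 (-1.75 after quantile normalization). AT5G63180, of the pectin lyase-like family, fell by 2.06, GH9B13, of the endoglucanase family, by 1.69, and ATSPS4F by 1.66. AT5G12110, of the translation elongation factor 1B family, fell by 1.75 and AT3G05060, a NOP58-like nucleolar protein gene, by 1.87. AT1G27020 and AT1G66940 fell by 2.18 and 1.76. After quantile normalization 9 of these 10 genes passed the threshold, and AT3G05060 did not (log2 change -1.59, limma adjusted p = 0.0568).

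Of the light-harvesting and Rubisco list, 4 of 5 members named here fell, 0 rose, and 4 fell when adjusted over the list alone. RCA, which encodes Rubisco activase, went from 2109 ± 87.7 to 1259.9 ± 41.5 (log2 change -0.74, SE 0.049), and LHCB4.3 from 676 ± 53.4 to 320.3 ± 46.3 (-1.05, SE 0.14). LHCB4.2 and LHCB4.1 fell by 0.38 and 0.37, close to the median change of -0.33 among the 3874 brightest probes, and after quantile normalization their changes were -0.11 and -0.055. LHCB4.3 kept most of its fall after quantile normalization without passing (-0.83, limma adjusted p = 0.0629), and RCA alone passed. LHCB1.5 had a log2 change of 0.17 that did not pass, was called higher after median centring (0.37) and lay at -0.31 under spike scaling. As a list these genes did not pass (camera adjusted p = 0.221, and adjusted p = 0.697 with an estimated correlation). The probe sets of RCA, LHCB4.1, LHCB4.2 and LHCB1.5 are of the kind that can bind related transcripts.

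A further list of photosystem, electron transport and Calvin cycle genes, written after the annotation was seen, had 3 of 7 named members lower and 0 higher, with 5 lower when adjusted over the list alone. SBPASE and PRK, which encode Calvin cycle enzymes, fell by 0.74 and 0.72, and ATPC1, a chloroplast ATP synthase subunit gene, by 0.43. The list lay below other genes by a mean of -0.27 (camera p = 0.00893, adjusted p = 0.0402), with p = 0.175 and adjusted p = 0.511 with an estimated correlation. After quantile normalization SBPASE alone passed and the list did not (camera adjusted p = 0.293).

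Among cytosolic ribosomal protein genes, 58 of the 128 members named here fell and 0 rose, with a median of -0.43, and 96 fell when adjusted over the list alone. The largest fall was that of AT5G48760, from 334 ± 12.6 to 147 ± 2.49 (log2 change -1.10, SE 0.039, limma adjusted p = 0.0167), followed by AT5G39850, which fell by 1.08. Under every scaling tried the median of this list stayed below 0 and no member was called higher: 19 fell after quantile normalization, 33 after median centring and 118 under spike scaling. Relative to other genes the list was lower by a mean of -0.31 (camera p = 3.56e-13 across n = 11371 genes, adjusted p = 6.41e-12). The call was lost with an estimated correlation (p = 0.324, adjusted p = 0.629). Of 5 named plastid ribosomal protein genes, 1 fell, AT1G64510 (-0.41), 5 fell when adjusted over the list alone, and the camera adjusted p was 0.115, or 0.668 with an estimated correlation.

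Of 3 chlorophyll synthesis genes, HEMB1, which encodes 5-aminolevulinate dehydratase, fell by 0.55, while PORB and CHLI2 had log2 changes of -0.24 and -0.27 that did not pass. Of 4 expansin and xyloglucan endotransglucosylase genes, EXPA8 fell by 0.70, but not past the threshold after quantile normalization (-0.44, limma adjusted p = 0.0882), EXPB1 changed by -0.38 without passing, and EXPA4 and XTH33 lay at -0.030 and 0.052, with signs that differ between scalings. None of 3 early auxin genes passed, LBD16 at 0.14 and GH3.3 at -0.037 among them, and the signs of both depend on the scaling. Adjusted over the list alone, 1, 1 and 0 members of these lists passed. Camera adjusted p-values were 0.221, 0.755 and 0.221, and 0.510, 0.782 and 0.510 with an estimated correlation.

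Lists with 1 or 2 named members were too small to test. WSD1, a wax ester synthase gene, rose by 0.85, from 36.1 ± 2.95 to 77.5 ± 5.00, and WRKY53, a transcription factor gene of senescence and defence, by 0.51. MCM7, a DNA replication helicase gene, fell by 0.50, but not past the threshold after quantile normalization (-0.19). Of the root markers, PYK10, a beta-glucosidase gene of roots and hypocotyls, went from 300.1 ± 28.8 to 112 ± 11.2 (log2 change -1.30), and EXPA7, a root hair expansin gene, was at 0.256 ± 0.114 and 1.66 ± 0.116, below the noise level of each array (7.54 or more), so its call carries no weight. BCAT4 and UGT74C1, of glucosinolate synthesis, changed by -0.59 and -0.79, the cytokinin response genes ARR15 by -0.46 and ARR16 by 0.064, with a sign that turns under spike scaling, and the stomatal lineage genes FAMA and MUTE by -0.50 and -0.23, none past the threshold. Neither DFR (-0.22) nor UF3GT (-0.019) of anthocyanin synthesis passed, nor did HSP22.0 (0.40), HSP15.7 (-0.080) or ProDH2 (-0.14), and the signs of DFR, UF3GT, HSP15.7 and ProDH2 differ between scalings. UGT71B6, an ABA glucosyltransferase gene, and SAND, a reference gene, were at or below 0 on each array. Adjusted over each list alone, ARR15, FAMA, BCAT4 and UGT74C1 passed as well.

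Over all 19371 probes, 769 were higher and 3805 lower after ABA, of which 263 and 390 changed at least 2-fold on this scale. Named genes made up 404 of the higher and 1974 of the lower calls, counted once per gene. The median log2 change of all probes was -0.13, and, with probes ranked by mean intensity, it ran from 0 among the 3875 dimmest to -0.33 among the 3874 brightest. With pseudocounts of 1 and 64 the median of all probes was -0.32 and -0.048, so the size of this shift depends on the pseudocount. How far the trend with intensity does so was not tested. Quantile normalization removes this shift by construction and so draws the split towards balance. It gave 892 higher and 1011 lower (53.1% lower, against 83.2% as deposited), of which 686 and 1011 were also called as deposited. Median centring, which adds 1 constant to each array, leaves the trend with intensity in place and moved the median of all probes to 0.070. Probes at or below 0 on every array, such as those of UGT71B6 and SAND, then had a change of 0.20. Median centring gave 1878 higher and 2424 lower (56.3% lower), and spike scaling 525 and 8085 (93.9% lower). Spike scaling used 1 factor per array, although the log2 ratios of the 9 spiked sets it used ran from 0.11 to 0.74. At 2-fold or more the split depended on the scaling, with 339 higher and 94 lower after quantile normalization, 443 and 164 after median centring, but 170 and 1949 under spike scaling. It also depended on the pseudocount on the deposited scale, with 456 higher and 1174 lower for 1 and 133 and 55 for 64. Leaving out any 1 of the 4 arrays ended all calls in limma, with 5780 to 6459 probes then at an unadjusted p under 0.05, against 7839 with all arrays. The changes themselves moved little, with LEA4-5 at 5.36 to 5.41 and a limma adjusted p of 0.0863 to 0.110, so 3 arrays were too few for a call even there.

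**Figure D2:**
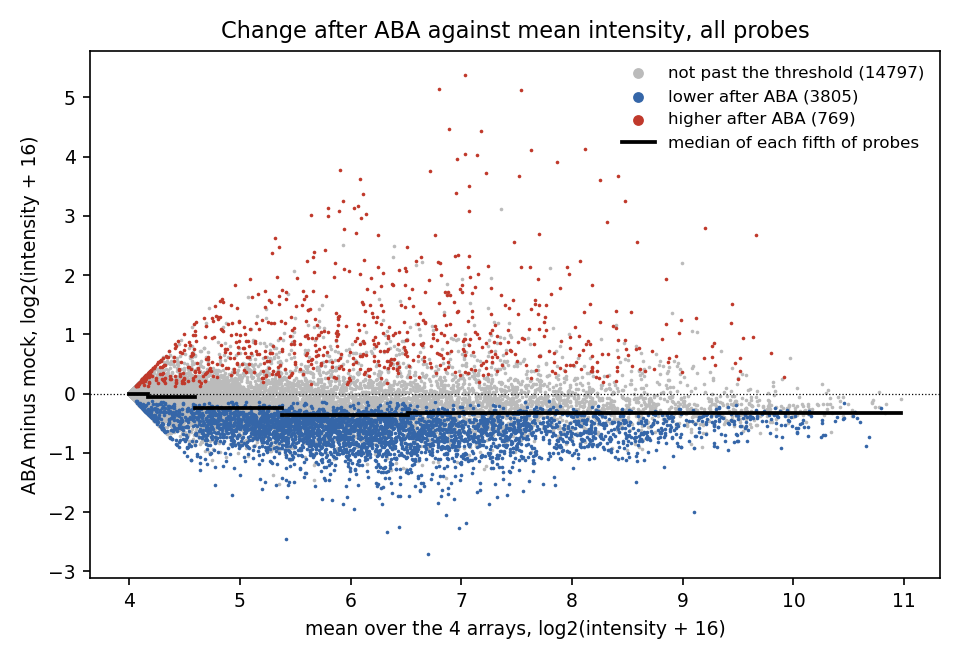
Change after ABA (ABA minus mock, log2(intensity + 16), vertical axis) against the mean over the 4 arrays (horizontal axis) for 19371 probes, 1 point each, with the 769 higher and 3805 lower probes coloured and black bars for the medians of 5 equal bins of probes. The medians of the 3 brighter bins lie at -0.24, -0.36 and -0.33 on the deposited scale, while the largest changes are increases.

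**Figure D3:**
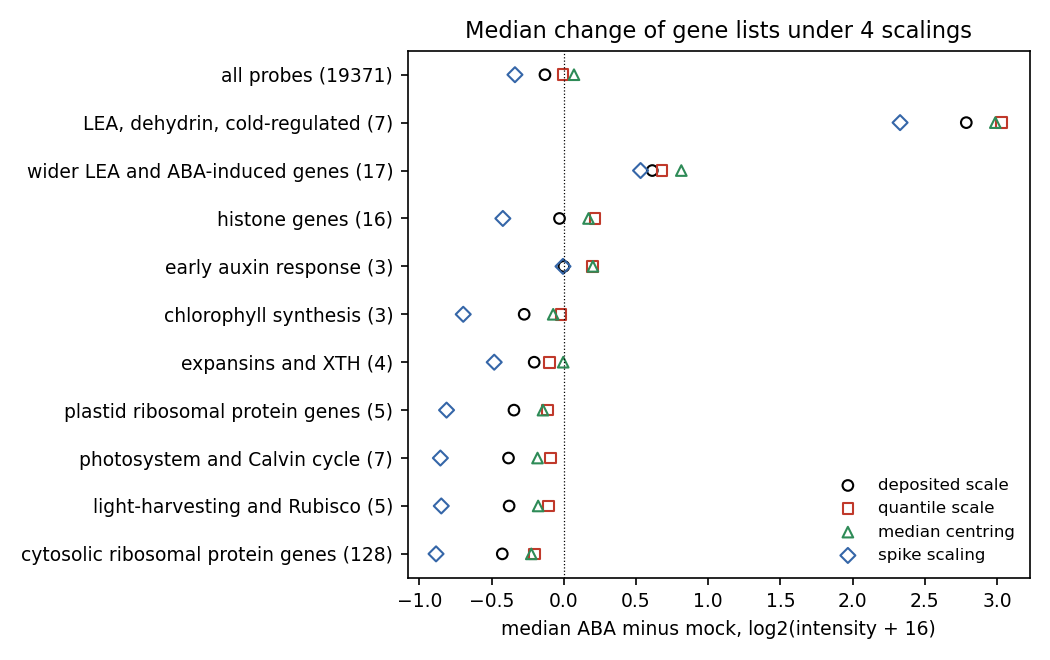
Median log2 change of all probes and of 10 gene lists (number of named members in brackets) under the deposited, quantile, median-centred and spike scalings. The LEA lists lie above 0 and the cytosolic ribosomal list below 0 under each of the 4 scalings, whereas the histone median runs from -0.42 under spike scaling to 0.22 after quantile normalization.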

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

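In this part, the test on spiked control sets was chosen only after the split of calls had been seen.

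A signal stood out among the 278 control sets that no test used. The 3' set for the bacterial lys transcript, a control that can be added to RNA before labelling, read 23.9 and 20.0 on the ABA arrays (mean 21.98) and 0.663 and 1.48 on the mock arrays. The other 2 sets for this transcript read 2.34 or less on each array, so the signal need not come from the lys transcript. The highest noise level of the 4 arrays, taken as the size of the 1st percentile of the tested probes, was 8.76. Some other control sets passed it on single arrays. The PheX 3' set read 27.9 on ABA replicate 1 and -2.96 on ABA replicate 2. The ThrX 5' set read 13.6 and 10.5 on replicate 2 of ABA and of mock, and below 0 on replicate 1 of both. Such sets thus varied between replicates as well, and the cause of the lys signal was not tested.

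More probes were lower than higher after ABA on the deposited scale. The most frequent log2 ratio of the 3874 brightest probes, taken without the added 16, was -0.35 (bootstrap interval -0.38 to -0.31), near their median of -0.36, which is consistent with 1 scale factor between the groups. A weaker signal of everything on the ABA arrays is argued against, because the 9 spiked hybridisation control sets used for spike scaling were all higher there. They rose by a median of 0.55 on the log2 scale, with a range of 0.11 to 0.74. The brightest of the 9, the CreX 3' set, rose least, so spike scaling by 1 factor may overstate the falls of bright probes. Further sets for the same spikes, marked dist in their names, were not among the 9 and also had higher means on the ABA arrays. On the log2(intensity + 16) scale they rose by 0.16 to 0.90, against 0.11 to 0.56 in the 9. The housekeeping control sets did not move by 1 factor, with actin at -0.38, GAPDH between -0.43 and -0.54, and ubiquitin at 0.045, 0.16 and -0.052. Less plant RNA hybridised per array and a lower transcript content after ABA both stay open, since no test here separates them.

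Cytosolic ribosomal protein genes were lower after ABA. If the array-wide shift were the whole cause, the list would lie within random lists of the same brightness. Its median of -0.43 instead lay at percentile 0.01 of 10000 such lists (95% between -0.36 and -0.22), and after quantile normalization its median of -0.20 did so too, against -0.13 to 0.0089. Genes of this list move together, with an estimated correlation of 0.558, so random lists may understate the chance spread, and the call was lost when camera allowed for it (p = 0.324). An effect of ABA on these genes stays open as a hypothesis.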

How the results depend on the processing

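Spike scaling, and quantile normalization with the filter for probes above the 40th percentile, were chosen after seeing the data. With 2 arrays per group the counts depend on scaling, filter and test, and the cause was not tested except where fewer probes give it. Against 4574 changed probes (769 higher, 3805 lower), quantile normalization gave 1903 (1011 lower), median centring 1878 higher and 2424 lower, the filter 5798 lower among 11622 probes, a floor of 32 gave 2625 (422 higher, 2203 lower), and 1 probe per gene 2057 (350 higher, 1707 lower). Spike scaling gave 8610 (8085 lower), and quantile normalization with the filter 1705 higher and 2293 lower. Treat against a change of 1.5-fold called 7 probes, 6 higher (LEA4-5, KIN1, AT1G16850, AT2G47780 and 2 unnamed here) and 1 lower, unnamed here, which were singled out after their values were seen. An adjusted p under 0.01 left 0, 0 higher and 0 lower, with 7839 probes at an unadjusted p under 0.05. Leaving out 1 array gave 0 to 0 calls, higher and lower alike, with the lone array assumed to vary like the other group. The labels do not say whether the replicate numbers mark pairs. The correlation of deviations (2 pairs, 0.0389) cannot decide it, since with 2 arrays per group the deviations mirror each other. The replicate block gave 0 calls in limma, 0 higher and 0 lower, with 7115 probes at an unadjusted p under 0.05. Pseudocounts of 1 and 64 and an intensity trend kept each of these counts within 1.5 times, but not those at 2-fold or more, which went from 263 higher and 390 lower to 456 and 1174 with a pseudocount of 1 and to 133 and 55 with 64.

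Camera called 1 of the 5 fixed lists, the LEA list. It called 2 with the floor of 32 (also light-harvesting genes, adjusted p = 0.0485), 0 with an estimated correlation, and fry, which asks whether members move 1 way on balance, called 4. The LEA list kept its direction under each alternative run, and its call under each except the estimated correlation. Of the 45 named genes, none past the threshold turned direction. All 30 of them that had passed lost their call under the block. The call was lost in 7 with the floor of 32 (WRKY53 and EXPA7 lie wholly below it) and in 6 after quantile normalization. Under each other alternative run for these genes on all 4 arrays, it was lost in 2 or fewer. Dim probes limit what can be seen: between 49.0% and 54.7% of probes lay below 16, the pseudocount.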

Other observations

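The ribosome biogenesis list in this part was chosen only after such genes had been seen among the lowest, and the gene families after the annotation had been seen.

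Families of metabolism held strong single responders. Of 40 UDP-glycosyltransferase (UGT) genes, 4 rose, namely UGT76E12 (log2 change 1.94), UGT84A1 (0.89), UGT84A3 (0.79) and UGT85A7 (0.64), and 6 fell, with UGT72E1 the lowest (-1.49) and UGT78D1 next (-0.82). After quantile normalization 5 were higher and 1 lower, so the balance turns with the scaling. Of 22 cytochrome P450 genes, CYP71B26 rose from 38.3 ± 9.34 to 187 ± 3.67 (1.91) and 4 fell, CYP71B35 by 0.82, CYP71B6 by 0.66, CYP71B36 by 0.40 and CYP71B34 by 0.30, and 1 was lower after quantile normalization. AT1G21400, which encodes a subunit of the branched-chain keto acid dehydrogenase, rose by 2.04, while MCCB and AT1G50110 of the same 7-gene breakdown list fell by 0.57 and 0.52 and did not pass after quantile normalization. None of 10 genes with a SWEET symbol passed, in contrast to SAG29, the SWEET transporter gene under another symbol.

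Of 18 TBL genes, a family of polysaccharide acetyltransferases, 6 fell and 1 rose, TBL38 (0.39). TBL45 fell by 1.23 and TBL36 by 1.15, and TBL25 fell as well (-1.10), of which TBL25 alone passed after quantile normalization. Of 18 serine carboxypeptidase-like genes 4 fell and of 15 beta-glucosidase (BGLU) genes 3 fell, BGLU28 by 0.92, BGLU33 by 0.85 and BGLU21 by 0.27, and 0 of either family were lower after quantile normalization. Of 16 histone genes 1 fell, HTB1 (-0.45), which did not pass after quantile normalization (-0.21), when another, AT5G10390, passed as higher (0.30). Of 8 root and root hair genes 3 fell, PYK10, AT1G05240 and AT1G30870, and EXPA7 was called higher, with 2 lower and 0 higher after quantile normalization. EXPA7 and AT1G30870 lay below the noise level of each array. The 3 SAUR and 11 TET genes held 0 calls, and the 14 PRA genes 1 higher, PRA8 (1.24). After quantile normalization PRA7 also passed (0.41) and the PRA list was called higher (camera adjusted p = 0.000957), while its median turned to -0.28 under spike scaling. On the deposited scale, the only one run with an estimated correlation, camera adjusted p-values of the families in these paragraphs lay between 0.0945 and 0.905, and between 0.511 and 0.908 with an estimated correlation.

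Ribosome biogenesis genes were lower after ABA, and the hypothesis tested was that genes of ribosome assembly may have been lowered as a group. Of 57 listed genes, none of them among the genes that prompted the list, 30 were named here, 21 fell and 0 rose, with AT5G14050 (-1.27), AT2G40700 (-1.25) and AT1G52930 (-1.06) at the low end. Their median of -0.74 lay at percentile 0 of 10000 random lists of the same brightness (95% between -0.45 and -0.15), and after quantile normalization it was -0.48, again at percentile 0, with 6 genes lower. The signal of 1 array pair alone is argued against, since the highest of the 4 array pairs' medians was -0.38 after quantile normalization. A correlation among these genes stays open, as camera gave p = 1.22e-07 but p = 0.190 with an estimated correlation. The same 4 arrays prompted the list, so this was not a test on new data, although the prompting genes are not in it.

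The control set for the E9 3' untranslated region, a terminator sequence used in plant vectors, read 23.7 and 30.9 on the ABA arrays and 85.9 and 105 on the mock arrays. The seedlings were wild type and the set's name marks it as able to bind related sequences, so what it bound is not known here. The sets for the CaMV 35S and NOS terminators lay at 3.55 or below on the 4 arrays.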
